A study of Mus musculus with 12 samples.

How the data were processed

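Polyadenylated RNA of cultured mouse 4T1 cells, a mammary carcinoma line, was sequenced in 12 libraries of 6 groups, with 2 libraries per group. The groups were control cells, knockout clone 1 and knockout clone 2, each grown on plastic (2D) or in collagen I gels (3D). Per the labels' protocols, the cells were nucleofected with sgRNA, the control cells were pools of clones given control sgRNA, and the knockout cells were single clones. Per the labels' protocols, 2D cells were collected directly, gels were digested with collagenase before RNA was taken, and libraries were made with a TruSeq Stranded mRNA kit. Collagen I of 1.2 or 2.4 mg/ml was used per the labels' protocols, and which library had which is not stated there.

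The deposited values are raw read counts per gene symbol, in 1 table for the 2D libraries and another for the 3D libraries, each with 31017 genes. Per the submitters' processing notes, the authors worked with FastQC 0.11.9, STAR 2.7.9a, featureCounts, R 4.1.1, Cell Ranger 3.0.0 and mouse genome build mm10, and the role of each tool and the strand setting of the counting are not stated there. The deposited counts were checked to be whole numbers with a different total in each library. Culture format, collagenase treatment and count table change together, so their effects cannot be told apart in any comparison of 3D with 2D.

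Gene positions and overlaps were taken from GENCODE M21 (mm10), which placed 13635 of the 13763 genes tested (99.07%). A kit that keeps strand does not show that the counting used it, so genes that overlap another gene on either strand were treated as uncertain. Histone genes, mt-Nd2 and AY036118 have near-identical copies that could share reads and were treated as uncertain too.

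Counts of both tables were joined by symbol and analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with few counts were removed with filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and a model with a mean for each of the 6 groups was fitted with edgeR's quasi-likelihood method. The fit had 6 residual degrees of freedom and a biological coefficient of variation of 4.51%. Every p-value for a gene is from edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested in that comparison, and the threshold was an adjusted p of 0.05. Log2 fold changes are given with their standard error (SE), and counts per M (CPM) with the standard deviation (SD) of 2 libraries.

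Knockout was compared with control in each format as the mean of both clones, and each clone was compared with the control and with the other clone. 3D was compared with 2D in the control and in the mean of both clones, and the interaction is the knockout difference in 3D minus that in 2D. The 5 main comparisons are the mean knockout contrast in each format, 3D against 2D in control and in knockout, and the interaction. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these libraries. Both clones were compared with the same control libraries. In 20 simulations both clones were left unchanged against those controls, which gives the overlap within a format from shared controls alone. The simulated clones had no changes of their own, so this is no chance level for long lists of called genes. Overlaps of both clones in both formats have only the value for independent lists beside them.

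Gene lists, 26 in number, were written before the data were examined. Each was tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), which compares a list with all other genes, and again with an estimated correlation, with a replicate block and with fry. List tests were planned for the 5 main comparisons, and those of single clones were added after the results were seen. Of 69 list calls made with the preset correlation, 64 were lost with an estimated correlation, and the 5 that held were the hypoxia, NF-kB and actin lists in the interaction, and the interferon list in clone 2 against control in 3D and in clone 2 against clone 1 in 3D.

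Named genes were chosen by a rule written before the data were examined. Etv4, Etv1 and Etv5 are given in every comparison. For knockout in each format and for 3D against 2D in control, the rule took the 10 genes up and the 10 down with the largest change among those past the threshold, also in each clone and in the same direction for knockout, with a mean of at least 5 CPM and an official symbol. The interaction has 5 up and 5 down, the other comparisons 3 up and 3 down, and each list described up to 4 members with the smallest p. Genes named from the set without overlap and genes nearly absent from a clone were chosen after their values were seen.

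A fold against a group with 0 counts is given as at least the fold over a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio is given with its 95% counting interval. These floors and intervals cover counting error only, and the fitted fold change of such a gene is no bound.

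Before the comparisons were run, the pipeline was tested on simulated data with 200 changed genes, with means and spread taken from the deposited counts. At a true fold of 2 it recovered 89.6% of the changed genes for knockout in 2D (13372 genes), 97.0% for knockout in 3D (13360 genes), 86.6% for the interaction (13359 genes) and 97.0% for 3D against 2D in control (13120 genes). For clone 1 against control in 2D (13366 genes) and clone 2 against clone 1 in 3D (13358 genes) it recovered 92.5% and 97.0%. At a true fold of 1.5 it recovered 74.6% for knockout in 2D, 85.1% for knockout in 3D, 73.1% for the interaction, 79.1% for 3D against 2D in control, 82.1% for clone 1 in 2D and 76.1% for clone 2 against clone 1 in 3D. In the same order the false calls were 6, 14, 8, 8, 12 and 17 genes, or 3.33%, 6.93%, 4.52%, 4.17%, 6.22% and 8.59% of the calls. Far more than 200 genes were called in each real comparison. Scaling, recovery and false calls with that many changed genes were not tested.

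The alternatives fixed before the data were examined were DESeq2's size factors, the DESeq2 1.42.0 Wald test, a looser and a stricter filter, a replicate block, each library left out in turn, and the libraries of 1 format fitted alone. Added later were a fit of genes that overlap no other gene, a fit without the transcripts Gm26917 and Gm42418, and a fit with each chromosome centred on its median in each clone. Summaries and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

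Libraries held 12.3 to 18.7 M counts in 2D and 26.5 to 33.2 M in 3D, so genes with few counts were measured less precisely in 2D. Within a group, the spread between the replicates was 3.54 to 9.63 times the variance that counting alone gives. No library and no gene beyond the filter was left out. Sequence variants, exon use and the edited alleles were not analysed here.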

Results

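RNA of 4T1 cells was measured in control cells and in 2 clones whose Etv4 gene, which encodes a transcription factor of the PEA3 group of ETS factors, had been targeted. Each was grown on plastic (2D) and in collagen I gels (3D), with 2 libraries per group. Control libraries held 13.9 and 14.4 M counts in 2D and 27.1 and 28.3 M in 3D. Those of clone 1 held 14.4 and 12.3 M in 2D and 27.6 and 33.2 M in 3D, and those of clone 2 held 18.7 and 14.4 M and 27.2 and 26.5 M. Reads fell on 13459 to 13875 genes per 2D library and on 17135 to 17595 per 3D library. The first principal component held 73.9% of the variance and set all 3D libraries apart from all 2D libraries. The second held 11.5% and set the clone 1 libraries apart from all others, and the third held 4.84% and set clone 2 apart from the control.

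Some abundant transcripts took different shares of the libraries of the 2 formats. Gm26917, a predicted gene, took 1.75 to 2.03% of the counts of the 2D libraries and 10.9 to 14.95% of those of the 3D libraries. Gm42418, another predicted gene, took 0.0971 to 0.129% in 2D and 1.45 to 1.95% in 3D. Genes of the mitochondrial genome took 0.314 to 0.515% and 1.45 to 1.76%. Ribosomal protein genes took 6.39 to 6.95% in 2D and 2.42 to 2.92% in 3D, and histone genes took 1.16 to 1.49% and 0.444 to 0.504%. The format, the collagenase step and the count table changed together, so none of these differences can be assigned to one of them.

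Etv4 (ENSMUSG00000017724.14, chromosome 11, 101769742 to 101785371, no overlapping gene) was the targeted gene. In 2D it was at 78.1 and 76.0 CPM in the control libraries, 49.8 and 49.2 in clone 1 and 49.3 and 46.0 in clone 2. In 3D it was at 94.7 and 99.4 CPM in control, 69.9 and 69.1 in clone 1 and 86.6 and 91.5 in clone 2. Small insertions or deletions can leave the count of a whole gene unchanged, so these values check the knockout little. In 2D Etv4 fell by 0.64 ± 0.07 on the log2 scale in clone 1 (adjusted p = 4.3e-08) and by 0.69 ± 0.07 in clone 2 (adjusted p = 2.2e-08). In 3D it fell by 0.48 ± 0.06 in clone 1 (adjusted p = 2.2e-07), to 71.6% of control, while the value in clone 2 was -0.12 ± 0.06 (adjusted p = 0.116). The mean of both clones was lower by a log2 change of -0.66 ± 0.06 in 2D (adjusted p = 2.0e-09) and -0.30 ± 0.05 in 3D (adjusted p = 4.4e-05). The genes of chromosome 11 had a median log2 change of -0.386 in 2D and -0.430 in 3D in clone 1 (802 genes), though single genes there rose, such as Cobl and Sparc. With each chromosome centred, Etv4 was at -0.05 in clone 1 in 3D (adjusted p = 0.541, and 1.5e-18 to 0.541 over all alternatives) and at -0.08 in the mean of the clones in 3D (adjusted p = 0.296, and 1.1e-11 to 0.296 over all alternatives). A fit of the 3D libraries alone gave -0.13 for Etv4 in clone 2 (adjusted p = 0.0128, and 0.0128 to 0.545 over all alternatives).

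Etv1 and Etv5, the other PEA3 members, moved differently from each other. Etv5 fell with Etv4 in clone 1 in both formats, while in clone 2 in 2D Etv4 fell and Etv5 did not. Etv1 (chromosome 12, 38779380 to 38870484) rose in the knockout in 2D by a log2 change of 0.51 ± 0.08 (adjusted p = 9.4e-06), with 0.52 in clone 1 and 0.50 in clone 2. The genes of chromosome 12 were also high in 2D, with medians of 0.208 in clone 1 and 0.207 in clone 2. With chromosomes centred, the rise of Etv1 in the 2D mean was smaller, at 0.30 (adjusted p = 0.0042). In 3D its mean change was 0.09 ± 0.05 (adjusted p = 0.211), with 0.02 in clone 1 (adjusted p = 0.804). Etv1 in clone 2 in 3D was at 0.16 ± 0.06 (adjusted p = 0.0463, and 0.0020 to 0.471 over all alternatives). This last call was lost without control replicate 2 in 3D (adjusted p = 0.471), clone 1 replicate 1 or 2 in 3D (0.0763 and 0.0575), or clone 2 replicate 1 or 2 in 3D (0.346 and 0.106). It was also lost with the DESeq2 Wald test (0.0602), with the looser filter (0.0618) and with chromosomes centred, at 0.08 (0.366). Etv5 (chromosome 16, 22381309 to 22439719) fell by 0.34 ± 0.07 in 2D (adjusted p = 0.00035) and by 0.40 ± 0.06 in 3D (adjusted p = 7.1e-06). The fall of Etv5 was in clone 1, at -0.71 ± 0.08 in 2D and -0.70 ± 0.07 in 3D, against 0.02 (adjusted p = 0.876) and -0.10 (adjusted p = 0.293) in clone 2. Chromosome 16 was also low in clone 1, with medians of -0.355 in 2D and -0.320 in 3D, and after centring Etv5 in the 2D knockout mean was at -0.11 (adjusted p = 0.261, and 5.3e-05 to 0.261 over all alternatives). Its other falls stayed past the threshold after centring, at -0.19 in the 3D mean (adjusted p = 0.024) and at -0.35 in 2D (0.0022) and -0.38 in 3D (8.9e-05) in clone 1, each the highest adjusted p over all alternatives.

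**Figure D1:**
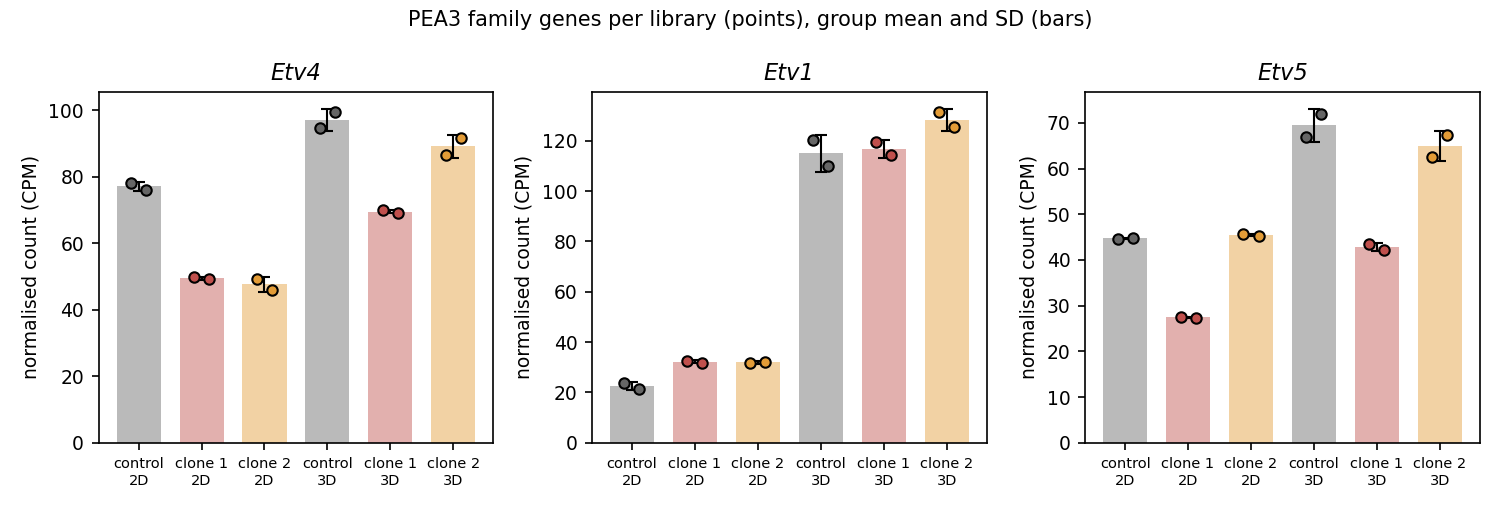
CPM of Etv4, Etv1 and Etv5 in the 6 groups. Bars are means of 2 libraries with the SD and points are single libraries, and Etv4 lies between 46.0 and 49.8 CPM in the clones in 2D against 76.0 and 78.1 in control.

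Knockout against control in 2D asks which genes differ between the Etv4-targeted clones and the control pool on plastic, and it cannot part effects of Etv4 from differences between clones. The genes that fell most in both clones included Slc39a4, a zinc importer, which fell by 4.80 ± 0.26 on the log2 scale (adjusted p = 1.5e-13), from 14.3 CPM in control to 0.295 in clone 1 and 0.793 in clone 2. Nlrc5, the transactivator of MHC class I genes, fell by 3.35 ± 0.14 (adjusted p = 1.4e-15), and Podnl1, a small leucine-rich matrix proteoglycan, fell by 3.29 ± 0.11 (adjusted p = 1.1e-17). Podnl1 dropped alike in the clones, from 62.7 CPM to 6.54 and 6.16. Mmp3, a secreted matrix protease, fell by 2.23 ± 0.09 (adjusted p = 7.7e-16), from 39.9 CPM to 11.8 and 6.08. Cldn7, a tight junction claudin, was at 59.5 CPM in control, 0.821 in clone 1 and 41.1 in clone 2, so its mean change of -3.35 ± 0.10 was carried by clone 1. Rps6ka6, a kinase of the RSK family, was likewise at -4.57 in clone 1 and -0.59 in clone 2. Cp (ceruloplasmin), Fam129a, Spata13 and Lgals3bp completed the 10 and fell by 2.40 to 2.85. Npr2, a receptor for natriuretic peptides, rose most, by 2.49 ± 0.23 (adjusted p = 5.8e-09), from 1.57 CPM to 11.8 and 6.67. Txnip, an inhibitor of thioredoxin, rose by 1.93 ± 0.14 (adjusted p = 7.2e-11), from 4.81 CPM to 17.0 and 19.97. Sirpa, the receptor of CD47, rose by 1.86 ± 0.13, with 2.88 in clone 1 and 0.84 in clone 2. Slc22a29, Cobl (an actin nucleator), Lypd3, Zfp575, Col12a1 (a fibril-associated collagen), Map6 and Ror1 (a receptor of the Wnt pathway) rose by 1.49 to 1.85. Txnip, Lypd3 and Npr2 are uncertain in part, since a gene on the opposite strand covers 19.4%, 13.6% and 5.70% of their exon length. Of 13763 genes tested, 2468 were higher and 2423 lower, and 164 and 548 of these changed by at least 2-fold. That near-even split turned to 2430 and 2442 with DESeq2's size factors, 2259 and 2598 without Gm26917 and Gm42418, 1684 and 2159 with chromosomes centred, and 1446 and 1628 with genes without overlap.

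Among the lists, the MHC class I genes, which present peptides to T cells, fell in the 2D knockout. Of 13 genes tested, 0 were higher and 11 lower (0 and 11 adjusted over the list alone), with Psmb8 at -1.86 ± 0.16, B2m at -0.44 ± 0.05, H2-K1 at -0.43 ± 0.05 and a median of -0.56. Psmb8 and Cxcl16 are uncertain in part, with 14.7% and 18.3% of their exon length covered on the opposite strand. The camera adjusted p of the MHC class I list was 2.5e-06, and adjusted p = 0.0595 with an estimated correlation. Cd74, the MHC class II invariant chain, had 93 counts in control, 0 in clone 1 (at least 28.5-fold lower) and 8 in clone 2. Hypoxia and glycolysis genes were higher in 13 of 22 and lower in 1 (13 and 2 adjusted over the list alone), with Pdk1, a brake on pyruvate oxidation, at 1.00 ± 0.06 and the glycolytic Aldoa at 0.57 ± 0.04, Pgk1 at 0.52 ± 0.05 and Ldha at 0.47 ± 0.05. Their median was 0.37 (0.34 with genes at the floor), with an adjusted p of 0.00037, and adjusted p = 0.0595 with an estimated correlation. NF-kB targets and chemokines were lower in 12 of 21 and higher in 1 (13 and 1 adjusted over the list alone), with the chemokines Cxcl3 at -2.07 ± 0.26 and Cxcl16 at -0.48 ± 0.05, and a median of -0.26. Cxcl16 lies on chromosome 11, and with chromosomes centred it was at -0.24 (adjusted p = 0.0012). That NF-kB list had an adjusted p of 0.0018, and adjusted p = 0.0595 with an estimated correlation. Its fall was mostly in clone 1, with 13 lower and 0 higher (14 and 0 adjusted over the list alone, median -0.49, adjusted p = 9.2e-05, and adjusted p = 0.064 with an estimated correlation), against 7 lower and 4 higher in clone 2 (7 and 6 adjusted over the list alone, median -0.14 and -0.16 with genes at the floor, adjusted p = 0.440). Clone 2 against clone 1 gave an adjusted p of 0.017 for the NF-kB list, and adjusted p = 0.173 with an estimated correlation. Fatty acid synthesis genes were lower in 9 of 11 and higher in 1 (9 and 1 adjusted over the list alone), with Fasn at -0.40 ± 0.04, Srebf1 at -0.49 ± 0.05 and Scd1 at -0.31 ± 0.05. Fasn, Srebf1, Acly and Acaca lie on chromosome 11, which had a median of -0.386 in clone 1. With chromosomes centred, Fasn was at -0.16 (adjusted p = 0.0062) and Srebf1 at -0.24 (0.0015), each the highest over all alternatives, and Acly was at -0.0059 (0.979, and 3.2e-10 to 0.979 over all alternatives). The median of the fatty acid list was -0.25 with an adjusted p of 0.0020, and adjusted p = 0.0595 with an estimated correlation. Actin and SRF targets were higher in 10 of 16 and lower in 2 (10 and 2 adjusted over the list alone), with the focal adhesion gene Zyx at 0.56 ± 0.06, Flna at 0.27 ± 0.04 and Cnn2 at 0.33 ± 0.06. The median was 0.23 but the mean -0.03, with an adjusted p of 0.013, and adjusted p = 0.1002 with an estimated correlation. Genes of the TGF-beta list were higher in 7 of 14 and lower in 2 (9 and 2 adjusted over the list alone). Among them were the HLH inhibitors Id2 at 1.42 ± 0.09, Id1 at 1.31 ± 0.10 and Id3 at 0.82 ± 0.06, and Ltbp2 at 0.78. The median of the TGF-beta list was 0.25 with an adjusted p of 0.015, and adjusted p = 0.354 with an estimated correlation. TGF-beta signalling itself was not measured. By clone, a choice made after the results were seen, MHC class I (adjusted p = 7.2e-05 in clone 1 and 1.5e-05 in clone 2) and hypoxia (8.2e-04 and 0.0011) passed in both. Fatty acid synthesis (0.114 and 9.9e-04), actin and SRF targets (0.163 and 0.0045) and TGF-beta targets (0.245 and 6.5e-04) passed in clone 2 but not in clone 1, though clone 2 against clone 1 did not pass for them (0.543, 0.530 and 0.676). With an estimated correlation these calls of single clones were lost (adjusted p of 0.0642 in clone 1 and 0.0754 to 0.173 in clone 2). Of the markers of other cell types, Cd68 was lower in the 2D knockout at -0.73 ± 0.26 (adjusted p = 0.033), Egfl7 lower at -0.56 ± 0.15 (0.0040) and Pdgfra higher at 0.55 ± 0.16 (0.0098), mostly in clone 1 (0.85 against 0.25 in clone 2). Csf1r had 20 counts in control, 0 in clone 1 and 31 in clone 2, and is uncertain in part, with 15.1% of its exon length covered on the opposite strand. The leukocyte, fibroblast and endothelial lists did not pass (adjusted p = 0.181, 0.165 and 0.319). Only 2, 1 and 1 of their members were tested, so these list tests cannot decide whether such markers changed. PEA3 and ERK feedback genes were higher in 2, lower in 6 and not called in 8 genes (median -0.17, adjusted p = 0.124). Matrix proteases and inhibitors went both ways, with 6 higher and 9 lower (median 0.08, mean -0.35, tested down with adjusted p = 0.763), among them Mmp10 at -2.22 ± 0.19, Mmp9 at -0.94 ± 0.08 and the membrane-bound Mmp14 at 0.53 ± 0.06. Matrix components were higher in 6 and lower in 8 (adjusted p = 0.884), with Sparc, a secreted collagen-binding protein, at -0.86 ± 0.06. Sparc was at 103 CPM in control, 165 in clone 1 and 19.7 in clone 2, so it rose in clone 1 and fell in clone 2.

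Knockout against control in 3D asks the same in collagen I gels, where Etv4 itself was not called lower in clone 2. Slc39a4 was again among the genes that fell most, by 4.89 ± 0.20 (adjusted p = 3.0e-16), from 17.9 CPM to 0.322 in clone 1 and 1.15 in clone 2. Podnl1 fell by 2.87 ± 0.11 (adjusted p = 2.4e-16), from 27.0 CPM to 4.00 and 3.35. Cav1 (caveolin 1) was at 54.2 CPM in control, 0.510 in clone 1 and 40.4 in clone 2, a mean change of -3.58 ± 0.10. Fam111a, which encodes a protease, had 3 counts in clone 1 against 1550 in control, a ratio of 536 with a counting interval of 183 to 2601, and it fell by 1.00 in clone 2. Atp1b1, a subunit of the sodium-potassium pump, fell by 2.63 ± 0.15, from 11.3 CPM to 3.20 and 1.04, with 18.7% of its exon length covered on the opposite strand. Akap12, a scaffold for protein kinase A, fell by 2.03 ± 0.11, from 23.8 CPM to 4.66 and 7.37. Rps6ka6, Fam129a, Dsc2 (a desmosomal cadherin) and Sp100 completed the 10 and fell by 1.93 to 2.48. For 3 of these the fall was mostly in clone 1. In control, clone 1 and clone 2, Rps6ka6 was at 35.4, 1.49 and 26.6 CPM, Dsc2 at 11.8, 1.07 and 8.23, and Sp100 at 16.1, 1.65 and 10.8. Sqor, a mitochondrial enzyme of sulfide oxidation, rose by 1.65 ± 0.18, from 2.26 CPM to 11.9 and 4.20. Sirpa rose by 1.44 ± 0.10, from 7.77 CPM to 30.1 and 14.8, and Npr2 rose by 1.38 ± 0.14, from 5.67 CPM to 17.1 and 12.8. Map6, Cobl, Mslnl, Neurl1a, Slc22a29, Megf6 and Pde5a rose by 1.21 to 1.29. Sparc was at 65.6 CPM in control, 77.9 in clone 1 and 1.53 in clone 2. In all, 1585 genes were higher and 2399 lower, and 72 and 354 of these changed by at least 2-fold. The split was 1893 and 2133 with DESeq2's size factors, 1949 and 2091 without Gm26917 and Gm42418, and 1260 and 1337 with genes that overlap no other gene. This total of 3984 was 2224 without control replicate 1 in 3D, 2109 without control replicate 2 in 3D, 6334 in a fit of the 3D libraries alone and 2398 with chromosomes centred.

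MHC class I genes were also lower in the mean of both clones in 3D, in 11 of 13 genes with 0 higher (11 and 0 adjusted over the list alone). Nlrc5 fell by 1.74 ± 0.10, Psmb8 fell by 1.57 ± 0.17, B2m fell by 0.46 ± 0.04 and H2-K1 fell by 0.41 ± 0.05. The median of that list was -0.45 with a camera adjusted p of 1.1e-05, and adjusted p = 0.119 with an estimated correlation. Most of this fall was in clone 1, with 12 genes lower and 0 higher (12 and 0 adjusted over the list alone, median -0.60, adjusted p = 3.6e-07, and adjusted p = 0.068 with an estimated correlation). In clone 2 in 3D 4 MHC class I genes were lower and 3 higher (4 and 4 adjusted over the list alone, median -0.06, adjusted p = 0.854), with Nlrc5 at -1.41 and B2m at -0.41 but Psmb8 at -0.19 (adjusted p = 0.453). YAP targets, read as a sign of mechanical signalling, were higher in 8 of 14 and lower in 2 (8 and 2 adjusted over the list alone). Among them the matricellular genes Cyr61 and Ctgf had mean changes of 0.81 ± 0.05 and 0.97 ± 0.08, and Arhgef17 of 0.48 ± 0.06. Cyr61 was at 115 CPM in control, 424 in clone 1 and 96.1 in clone 2, so it rose in clone 1 and fell in clone 2, and Ctgf rose in both, from 14.8 CPM to 33.5 and 25.1. Their median was 0.15 with an adjusted p of 0.020, and adjusted p = 0.326 with an estimated correlation. In clone 1 YAP targets were higher in 7 and lower in 2 (7 and 2 adjusted over the list alone, adjusted p = 0.032, and adjusted p = 0.161 with an estimated correlation), a call lost with a replicate block (adjusted p = 0.0643). In clone 2 they were higher in 4 and lower in 3 (4 and 3 adjusted over the list alone, adjusted p = 0.654), and clone 2 against clone 1 did not pass (adjusted p = 0.0997). Matrix components were higher in 3 genes, lower in 10 and not called in 11 (adjusted p = 0.0972), with Sparc at -2.58 ± 0.07, fibronectin (Fn1) at -0.57 ± 0.05 and Col6a1 at -1.09 ± 0.11. Matrix proteases and inhibitors were higher in 7 and lower in 3 (median 0.07, mean -0.09, tested up with adjusted p = 0.278), with the collagenase Mmp13 at -1.32 ± 0.13, Mmp14 at 0.47 ± 0.05 and Mmp3 at 0.39 ± 0.06. The clones parted in this list. In clone 1 13 were higher and 5 lower (13 and 5 adjusted over the list alone, median 0.35, adjusted p = 0.014, and adjusted p = 0.146 with an estimated correlation), and in clone 2 3 were higher and 10 lower (3 and 11 adjusted over the list alone, median -0.16, adjusted p = 0.0982). Clone 2 against clone 1 gave an adjusted p of 0.0087 for matrix proteases and inhibitors in 3D, and adjusted p = 0.158 with an estimated correlation. Mmp3 was at 60.9 CPM in control, 192 in clone 1 and 33.2 in clone 2. NF-kB targets were higher in 6 and lower in 4 (median 0.10, mean -0.04, tested up with adjusted p = 0.228), with the neutrophil chemokines Cxcl1 at 0.97 ± 0.05 and Cxcl5 at 0.70 ± 0.07. In clone 2 12 NF-kB targets were higher and 4 lower (12 and 4 adjusted over the list alone, median 0.45, adjusted p = 0.026, and adjusted p = 0.171 with an estimated correlation), and in clone 1 4 were higher and 7 lower (4 and 8 adjusted over the list alone, median -0.32, adjusted p = 0.835), while clone 2 against clone 1 did not pass (adjusted p = 0.304). Hypoxia genes were higher in 1 and lower in 9 (median -0.13, adjusted p = 0.0972), and cell cycle genes were higher in 2 and lower in 10 (adjusted p = 0.1099). The clones parted in the cell cycle list in 3D. In clone 1 14 of its genes were higher and 5 lower (16 and 6 adjusted over the list alone, median 0.18, adjusted p = 0.019, and adjusted p = 0.449 with an estimated correlation), with the proliferation marker Mki67 at 0.64 ± 0.06. In clone 2 0 were higher and 20 lower (0 and 22 adjusted over the list alone, median -0.30, adjusted p = 2.4e-10, and adjusted p = 0.103 with an estimated correlation), with Mki67 at -0.22 ± 0.06. These tests of single clones were chosen after the results were seen.

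**Figure D2:**
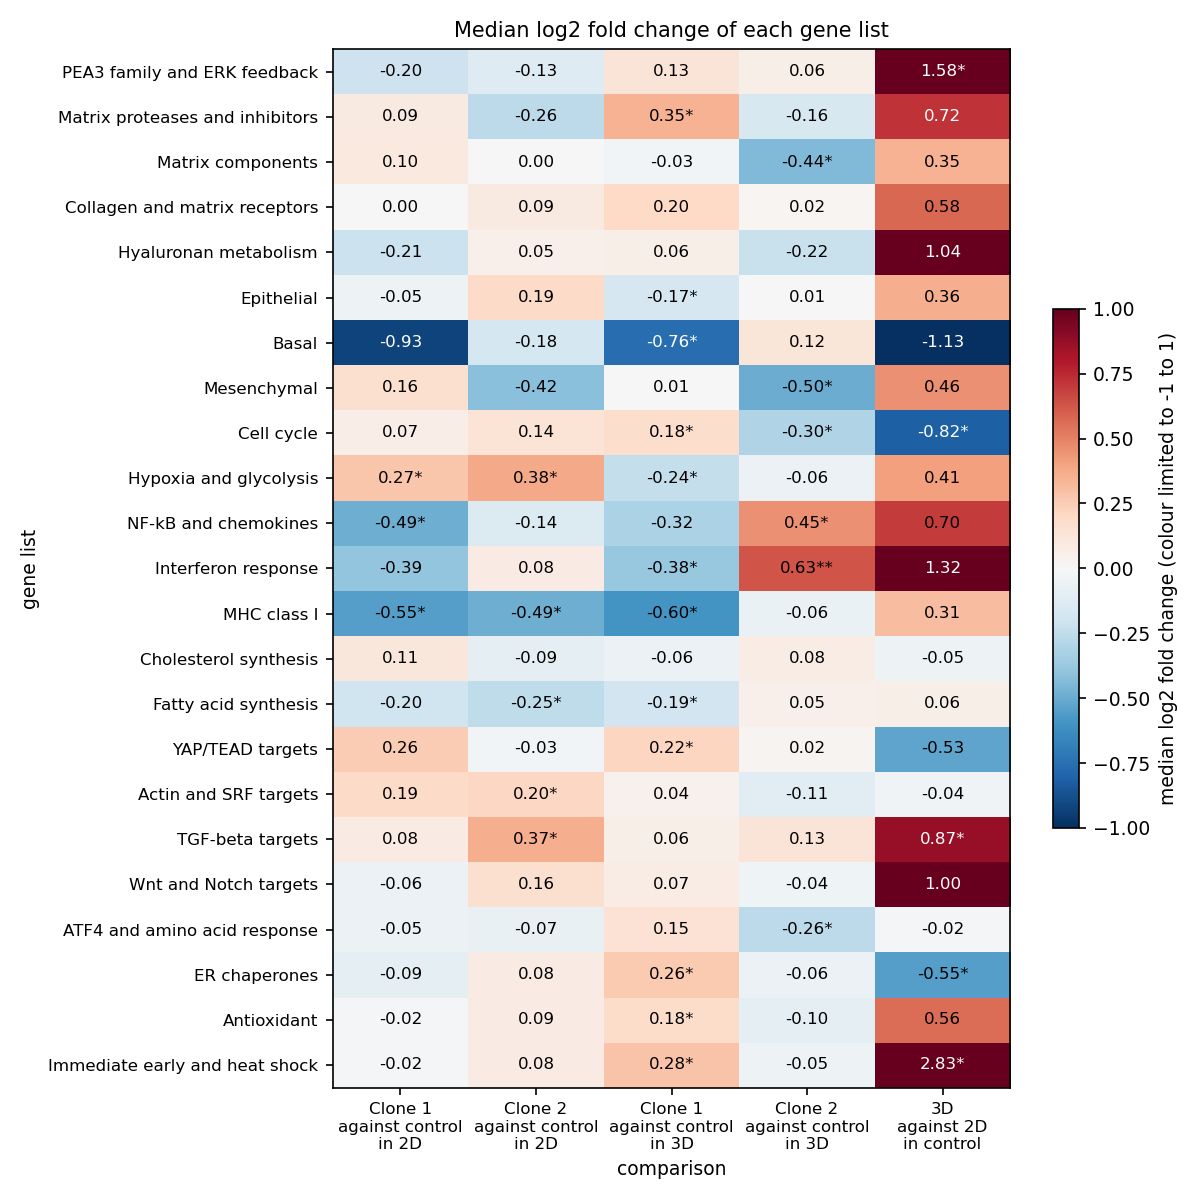
Median log2 fold change of each list with at least 5 members tested (rows) in clone 1 and clone 2 against control in 2D and in 3D and in 3D against 2D in control (columns), with the colour limited to -1 to 1. One star marks a camera adjusted p under 0.05 with the preset correlation and a pair of stars one that also held with an estimated correlation, and the interferon list in clone 2 in 3D (median 0.63) has a pair.

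The clones were compared for how far they moved alike. In 2D, 1081 genes were higher and 939 lower in both clones, where 513 and 413 would be shared by independent lists, and 500 changed in opposite directions, where 927 would. In 3D, 381 were higher and 607 lower in both, where 360 and 550 would be shared by independent lists, and 1359 changed in opposite directions, where 903 would. Simulated unchanged groups against the same controls gave a mean of 0.05 genes in 2D and 0 in 3D called alike in both. The simulated clones had no changes of their own, so this is no chance level for lists of this length. Across 9761 genes with a mean of at least 5 CPM, the fold changes of the clones had a correlation of 0.34 in 2D and -0.11 in 3D. Simulations of shared controls gave 0.51 and 0.50, but simulated fold changes hold noise only, so these are no level for the observed correlations. The covariance of the observed fold changes was 0.0737 in 2D (0.00930 simulated) and -0.0185 in 3D (0.00451 simulated), and genes are not independent replicates. With 2 control libraries per format, the controls were not split, and part of any excess may come from sharing them. Podnl1 and Slc39a4 fell in both clones in both formats, as did 277 genes in all (41.4 for independent lists), and 163 rose in both clones in both formats (29.9 for independent lists), Npr2 among them. Cldn7 and Sparc went with a clone, Cldn7 with -5.13 ± 0.10 in clone 1 in 3D and Sparc with -5.41 ± 0.10 in clone 2 in 3D. The 500 genes with opposite changes in 2D were 332 without control replicate 2 in 2D. The 988 called alike in 3D were 558 and 521 without control replicate 1 or 2 in 3D and 590 and 596 without clone 2 replicate 1 or 2 in 3D, and the 1359 with opposite changes were 684, 679, 838 and 829 without these libraries.

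**Figure D3:**
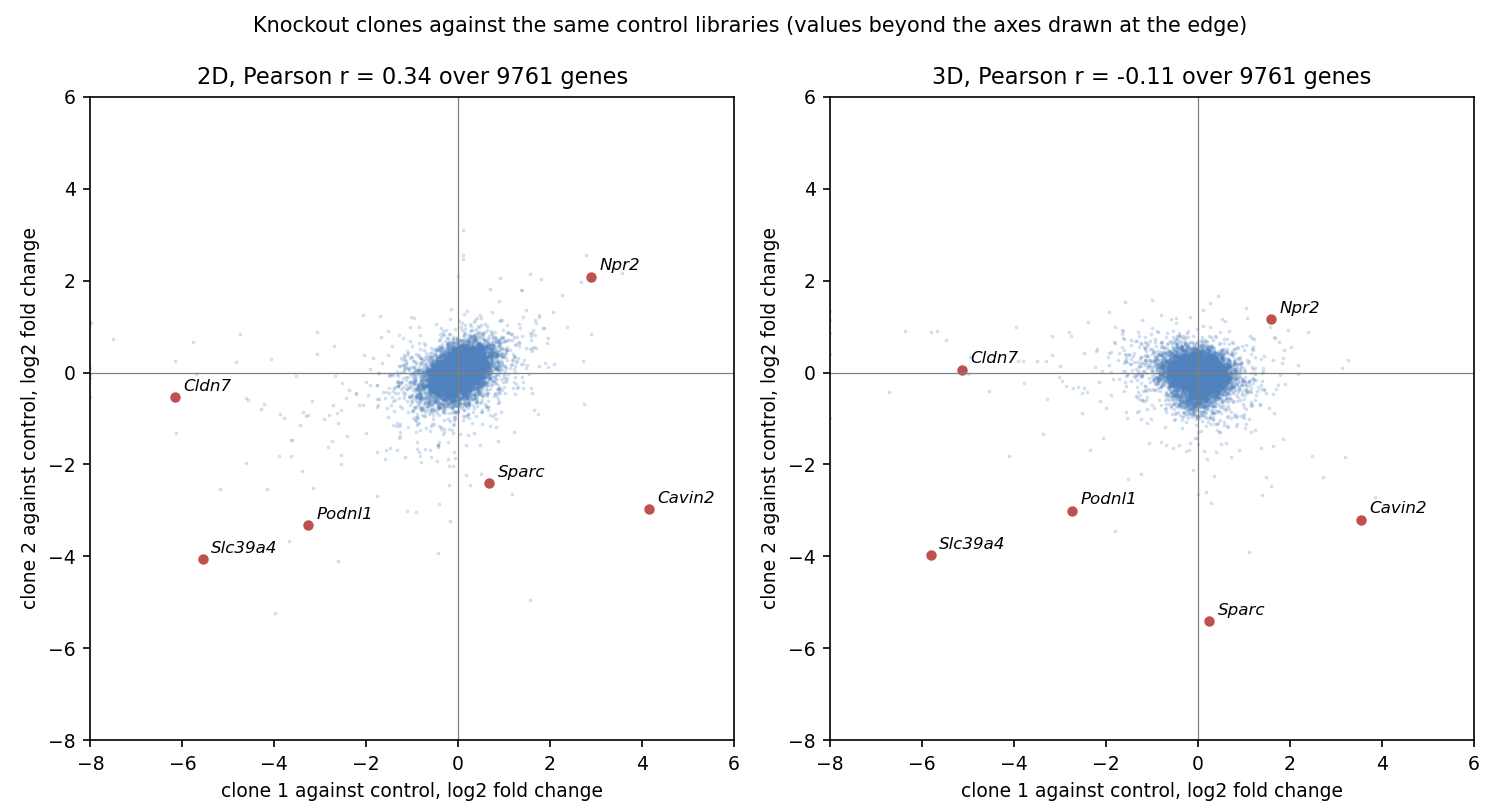
Log2 fold change against control of clone 2 (y) against clone 1 (x) for 9761 genes in 2D and in 3D, with values beyond the axes drawn at the edge. Each point is a gene, the correlation across genes is 0.34 in 2D and -0.11 in 3D, and 6 genes are named.

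**Figure D4:**
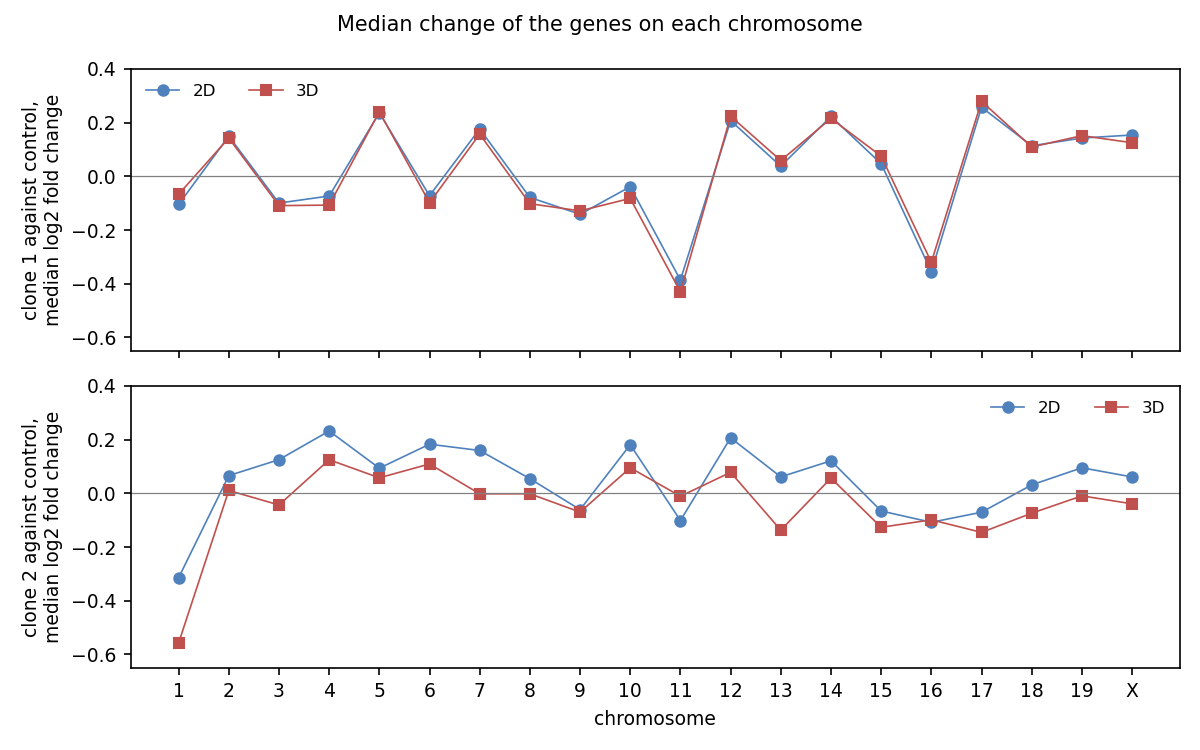
Median log2 fold change against control of the genes of each of 20 chromosomes in clone 1 (top) and clone 2 (bottom), in 2D and in 3D. Chromosome 11 is lowest in clone 1 (-0.386 and -0.430) and chromosome 1 is lowest in clone 2 (-0.315 and -0.558).

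Clone 2 against clone 1 answers how far the knockout clones differ from each other. Cavin2, a coat protein of caveolae, was at 21.1 CPM in control, 375 in clone 1 and 2.59 in clone 2 in 2D, a difference of -7.13 ± 0.13 between the clones (adjusted p = 2.9e-24). In 3D it was at 4.81, 56.6 and 0.519 CPM, a difference of -6.76 ± 0.17. Col5a1, a fibrillar collagen chain, was lower in clone 2 in 2D by a log2 change of -3.81 ± 0.12, and Pcsk6, a proprotein convertase, by -3.41 ± 0.15 in 2D and -6.57 ± 0.18 in 3D. Tnxb (tenascin X) was at 0.415 CPM in control, 13.6 in clone 1 and 0.122 in clone 2 in 3D. Fam111a, Bspry and Zfp979 had 0 counts in clone 1 in 2D and were at least 382-fold, 179-fold and 103-fold higher in clone 2. In 3D the glypican Gpc4, Zfp518b and Rasef had 0 counts in clone 1 and were at least 645-fold, 540-fold and 485-fold higher in clone 2. Etv4 differed between the clones by -0.05 ± 0.07 in 2D (adjusted p = 0.603) and by 0.36 ± 0.06 in 3D (adjusted p = 1.2e-05). Centring of chromosomes changed both of these calls for Etv4, to -0.34 in 2D (adjusted p = 5.7e-04, and 5.7e-04 to 1.0 over all alternatives) and to -0.06 in 3D (adjusted p = 0.431, and 5.7e-12 to 0.431 over all alternatives). Etv5 was higher in clone 2 by 0.73 in 2D and 0.60 in 3D. Etv1 in 3D was at 0.14 (adjusted p = 0.0533), and it passed the threshold without control replicate 1 or 2 in 2D (adjusted p = 0.0336 and 0.0337) or clone 1 replicate 1 or 2 in 2D (0.0495 and 0.0488), with 3.0e-04 to 0.438 over all alternatives. It also passed with a replicate block (0.0434), with the stricter filter (0.0112), with the 3D libraries fitted alone (0.0027) and with chromosomes centred, at 0.28 (3.0e-04). In 2D 3194 genes were higher and 2538 lower in clone 2, 505 and 409 of them by at least 2-fold, and in 3D 3633 and 3920, 922 and 534 of them by at least 2-fold. The balance of these calls turned with chromosomes centred, to 2259 and 2400 in 2D and 3354 and 3073 in 3D. In 2D it was 2975 and 2760 with DESeq2's size factors and 2907 and 2837 without Gm26917 and Gm42418.

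Lists tested between the clones, a choice made after the results were seen, set the epithelial genes of clone 2 above those of clone 1 in 2D. Of 21 genes 13 were higher and 4 lower (13 and 5 adjusted over the list alone), with Cldn7 at 5.63 ± 0.17, the adhesion molecule Epcam at 1.02 ± 0.05, the splicing factor Esrp1 at 0.96 ± 0.06 and the keratin Krt8 at 0.73 ± 0.05. The median was 0.38 with an adjusted p of 0.012, and adjusted p = 0.17 with an estimated correlation. In 3D the interferon response genes of clone 2 were above those of clone 1 in 16 of 21 genes and below in 1 (16 and 1 adjusted over the list alone), with the RNA sensor Ddx60 at 3.49 ± 0.15 and Oasl2 at 2.36 ± 0.13. Their median was 0.96 with an adjusted p of 4.5e-06, and adjusted p = 0.036 with an estimated correlation. Cell cycle genes in 3D were lower in clone 2 in 22 of 26 and higher in 0 (23 and 0 adjusted over the list alone), with the replication licensing genes Mcm3 at -0.93 ± 0.05 and Mcm6 at -0.95 ± 0.05. With chromosomes centred, Mcm3 was at -0.44 and Mcm6 at -0.46. The median of the cell cycle list was -0.51 with an adjusted p of 1.7e-07, and adjusted p = 0.11 with an estimated correlation.

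3D against 2D in control answers which genes differ between gel and plastic culture without knockout. Egr1, an immediate early transcription factor, rose by 9.18 ± 0.10, from 0.998 to 581 CPM, and the AP-1 members Fos and Fosb rose by 8.83 ± 0.13 and 8.34 ± 0.15, from 0.817 to 379 CPM and from 2.28 to 737 CPM. Egr3, a relative of Egr1, and Klf2, a Kruppel-like factor, rose by 7.52 ± 0.29 and 7.06 ± 0.14. Nnat (neuronatin) had 0 counts in 2D and 805 in 3D, at least 141-fold higher. The cover given for genes here counts exons only, so a gene inside an intron of an opposite-strand gene carries no such flag. Reads of such a host gene are therefore not excluded as the source of the 3D counts of Nnat. Mfsd4a, a transporter, had 2 counts against 4595, a ratio of 1209 with a counting interval of 335 to 9990, and 23.9% of its exon length is covered on the opposite strand. Pycard, the inflammasome adaptor, had 1 count against 580, a ratio of 305 (54.6 to 12080). Mroh2a and Scara5, a scavenger receptor, had 3 counts each in 2D, with ratios of 175 (59.6 to 849) and 156 (53.3 to 759). The 10 genes that fell most are uncertain, since 56% or more of the exon length of each is covered by a gene on the opposite strand. They were Hist2h2bb, AY036118, Hist2h3b, Pdcd2, Med10, Pus3, Hist1h4b, Gnpnat1, Ilk and Slirp. Ilk, the integrin-linked kinase, was at 70.3 CPM in 2D and 0.957 in 3D with 89.7% of its exons covered, and Pdcd2 at 42.7 CPM and 0 counts with 100% covered. Among genes that overlap no other gene, a set chosen after the values were seen, the stress gene Gadd45b fell by 4.21 ± 0.10, from 84.8 to 4.57 CPM, and the DNA repair endonuclease Apex1 fell by 4.04 ± 0.07, from 167 to 10.2 CPM. Fgfbp1, a carrier of fibroblast growth factors, fell by 2.68 ± 0.09, and Cdkn1a, the cell cycle inhibitor p21, rose by 6.16 ± 0.20, from 0.752 to 54.5 CPM. Etv4 rose by 0.33 ± 0.06 (adjusted p = 2.7e-05), Etv5 by 0.63 ± 0.07 and Etv1 by 2.35 ± 0.08, the last from 22.5 ± 1.68 to 115 ± 7.30 CPM (SD, n = 2). In total 5735 genes were higher and 4893 lower, 3405 and 1808 of them by at least 2-fold, and the median change of all genes was 0.102.

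**Figure D5:**
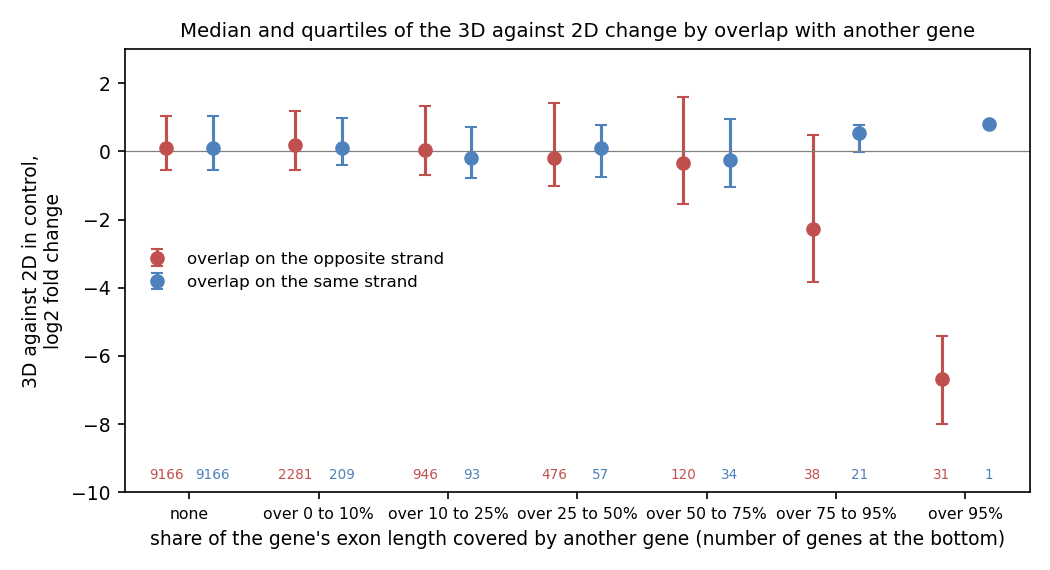
Median and quartiles of the log2 fold change of 3D against 2D in control (y) by the share of a gene's exon length covered by another gene (x), on the opposite strand (red) or the same strand (blue), with gene numbers at the bottom. The 31 genes over 95% covered on the opposite strand have a median of -6.66, against 0.1097 for 9166 genes with no overlap.

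Genes of the PEA3 family and of ERK feedback rose in 3D in control in 15 of 16 and fell in 1 (15 and 1 adjusted over the list alone). Only the 3D cells were treated with collagenase, so this rise cannot be assigned to the gel. Egr1 and Ier3 of this list are also in the immediate early list. The AP-1 member Fosl1 rose by 2.97 ± 0.07, Spred2, a brake on ERK signalling, by 3.19 ± 0.09 and Phlda1 by 2.56 ± 0.08, with a median of 1.58. Fosl1 and Phlda1 are uncertain, with 57.2% and 33.0% of their exon length covered on the opposite strand. The camera adjusted p was 8.7e-05, and adjusted p = 0.234 with an estimated correlation. Immediate early and heat shock genes rose in 19 of 24 and fell in 4 (19 and 4 adjusted over the list alone), with Ier2 at 4.35 ± 0.07 and a median of 2.83. Their adjusted p was 5.8e-04, and adjusted p = 0.174 with an estimated correlation. Cell cycle genes fell in 24 of 26 and rose in 1 (24 and 1 adjusted over the list alone), with the mitotic kinase Cdk1 at -1.38 ± 0.05, the cyclins Ccnb1 at -1.33 and Ccna2 at -1.25, and Cdc20 at -1.43. Their median was -0.82 with an adjusted p of 2.1e-06, and adjusted p = 0.271 with an estimated correlation. TGF-beta targets rose in 12 of 14 and fell in 2 (12 and 2 adjusted over the list alone), with the ligand Tgfb1 at 4.20 ± 0.13 and the feedback inhibitor Smad7 at 1.37 ± 0.06. Their adjusted p was 0.032, and adjusted p = 0.391 with an estimated correlation. ER chaperones fell in 12 of 16 and rose in 3 (12 and 3 adjusted over the list alone), with Pdia6, a disulfide isomerase, at -1.03 ± 0.05 against Dnajb9 at 2.49 ± 0.13. Their adjusted p was 0.049, with adjusted p = 0.391 with an estimated correlation and 0.0519 with a replicate block. With genes that overlap no other gene, the PEA3, cell cycle and immediate early lists stayed past the threshold (adjusted p = 0.00055, 0.00013 and 0.0015), and TGF-beta targets (0.0649) and ER chaperones (0.0627) did not. Matrix receptors, among them the integrin chains Itgb4 at 2.38 ± 0.06 and Itga5 at 1.95 ± 0.11 and the hyaluronan receptor Cd44 at 1.88 ± 0.06, were higher in 13 of 17 and lower in 3, but the list did not pass (adjusted p = 0.0600). YAP targets were higher in 3 and lower in 9 of 14, with Ctgf at -2.32 ± 0.09, and did not pass (adjusted p = 0.0600). Markers of other cell types were mostly too low to test, with 1 of 11 fibroblast, 2 of 12 leukocyte and 1 of 9 endothelial markers tested. Pdgfra, the fibroblast marker tested, rose from 3.67 to 21.4 CPM, and the macrophage marker Cd68 from 3.77 to 7.91 CPM. Csf1r was at -0.34 (adjusted p = 0.597), and the endothelial Egfl7 fell by 1.80 ± 0.18.

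3D against 2D in the knockout asks the same of the mean of both clones. Etv4 rose by 0.69 ± 0.05 (adjusted p = 1.4e-13), Etv1 by 1.93 ± 0.05 and Etv5 by 0.58. Nnat and the keratin Krt87 had 0 counts in 2D and were at least 341-fold and 222-fold higher in 3D. Genes inside introns carry no flag here either, so reads of a host gene are not excluded for these genes. Sptb, a spectrin chain of the membrane skeleton, had 1 count in 2D against 2190 in 3D, a ratio of 1144 with a counting interval of 205 to 45221. Hist2h2bb, Hist2h3b and AY036118 fell most, and they are uncertain for the reasons given for the control. PEA3 and ERK feedback genes rose in 15 of 16 and fell in 1 (15 and 1 adjusted over the list alone, median 1.81, adjusted p = 7.8e-05), and cell cycle genes fell in 24 of 26 and rose in 1 (24 and 1 adjusted over the list alone, median -0.90, adjusted p = 6.3e-07). NF-kB targets rose in 17 of 21 and fell in 3 (17 and 4 adjusted over the list alone), with Cxcl1 at 2.29 ± 0.04, Lif at 2.12 ± 0.05 and Nfkbiz at 2.29 ± 0.05, a median of 1.41 (1.12 with genes at the floor) and an adjusted p of 0.023. Immediate early and heat shock genes rose in 19 of 24 and fell in 4 (19 and 4 adjusted over the list alone, median 3.26, adjusted p = 0.0018). These 4 lists had adjusted p = 0.162 with an estimated correlation. Of all genes 6176 were higher and 5295 lower, 3618 and 1948 of them by at least 2-fold. Across 9761 genes the changes in knockout and in control had a correlation of 0.974, and 5337 genes were higher and 4568 lower in both, where 2574 and 1882 would be shared by independent lists. The groups share no library, but genes are not independent replicates.

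The interaction answers whether the knockout difference in 3D departs from that in 2D. Sparc, at 103 CPM in control, 165 in clone 1 and 19.7 in clone 2 in 2D and at 65.6, 77.9 and 1.53 in 3D, had an interaction of -1.72 ± 0.10 (adjusted p = 6.6e-12). Txnip was at -1.95 ± 0.16 (adjusted p = 7.4e-09), higher than control in both clones in 2D but at 49.1 CPM in control, 24.6 in clone 1 and 95.4 in clone 2 in 3D. Id2, a member of the TGF-beta list, was at -1.48 ± 0.12 (adjusted p = 3.5e-09). The complement gene C3 was at 3.05 ± 0.20 (adjusted p = 7.5e-11) and Neurl3 at 3.35 ± 0.35 (adjusted p = 3.6e-07), both far below control in the clones in 2D. Mmp3 was at 2.62 ± 0.11 and Mmp10 at 2.08 ± 0.23, and the protease list did not pass (5 higher and 2 lower of 22, adjusted p = 0.111). Etv4 itself was at 0.36 ± 0.08 (adjusted p = 0.0040), and at 0.31 without control replicate 1 in 3D (adjusted p = 0.0624, and 8.5e-04 to 0.0624 over all alternatives). Etv1 was at -0.42 ± 0.09 (adjusted p = 0.0050) and Etv5 at -0.06 ± 0.09 (adjusted p = 0.797). Hypoxia genes were lower in 11 of 22 and higher in 0 (15 and 1 adjusted over the list alone), with Pdk1 at -0.89 ± 0.09, Ldha at -0.67 ± 0.07 and the mitophagy receptor Bnip3 (22.3% covered on the opposite strand) at -1.10 ± 0.11. Their median was -0.50 (-0.46 with genes at the floor), with an adjusted p of 3.0e-09, and adjusted p = 0.0121 with an estimated correlation. NF-kB targets were higher in 8 of 21 and lower in 0 (8 and 0 adjusted over the list alone), with Cxcl1 at 1.15 ± 0.08, Cxcl5 at 1.28 ± 0.10 and Cxcl16 at 0.69 ± 0.07. Their adjusted p was 9.2e-08, and adjusted p = 0.0121 with an estimated correlation. Actin and SRF targets were lower in 10 of 16 and higher in 0 (11 and 1 adjusted over the list alone), with Cnn2 at -0.71 ± 0.08 and Actg1 at -0.49 ± 0.06 (adjusted p = 1.9e-04, and adjusted p = 0.0400 with an estimated correlation). Of 1102 genes past the threshold 389 were higher and 713 lower, and other scalings moved this split to 459 and 527 with DESeq2's size factors and to 527 and 459 without Gm26917 and Gm42418. The total was 550 and 415 without control replicate 1 or 2 in 3D, 589 without clone 1 replicate 2 in 3D and 644 without clone 2 replicate 1 in 3D.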

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

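The tests of recurring chromosome medians, of a single scaling factor, of exchanged clones and of Etv4 after centring were chosen after the results were seen, as was the centred fit itself. Each result here is either a knockout difference that departed between 3D and 2D by the interaction test, or a difference between the clones by a direct test or by calls in opposite directions.

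Between the clones 5732 genes differed in 2D and 7553 in 3D, and 500 genes in 2D and 1359 in 3D were called against control in opposite directions. Cldn7, Cav1 and Rab25 were nearly absent from clone 1 but not from clone 2, while Sparc was at 77.9 CPM in clone 1 and 1.53 in clone 2 in 3D. The median change differed between chromosomes in each clone, and over 20 chromosomes the medians in 2D and 3D had a Pearson r of 0.991 in clone 1 and 0.864 in clone 2 (Spearman's rho 0.968 and 0.820, Pearson permutation p = 1e-05 in each, the smallest possible). These r were 0.987 and 0.767 without the 2 chromosomes farthest from the median. The range of chromosome medians was at least 0.547, against at most 0.167 with genes shuffled over chromosomes, so 1 scaling factor per library is excluded as its cause, and copy number of chromosomes may be a cause.

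After each chromosome was centred, 749 of the 1359 genes with opposite calls in 3D (55.1%) and 182 of 500 in 2D (36.4%) were still called so, which argues against whole-chromosome copy number as the whole cause of the opposite calls. Exchanged clones were excluded, since each clone's changes in 2D had a correlation with its own in 3D that was higher than with the other clone's by at least 0.302. Differences that single cells carried before cloning, effects of the edit that differ between alleles, and copy number of smaller segments stay open, and no biological explanation was tested. The 500 genes were 332 without control replicate 2 in 2D, and the 1359 were 684 and 679 without control replicate 1 or 2 in 3D and 838 and 829 without clone 2 replicate 1 or 2 in 3D.

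Etv4 had an interaction of 0.36 ± 0.08 (adjusted p = 0.0040), and 0.31 without control replicate 1 in 3D (adjusted p = 0.0624, and 8.5e-04 to 0.0624 over all alternatives). In clone 1 it lies on the chromosome with the lowest median, and its 181 neighbours within 10 Mb had medians of -0.446 in 2D and -0.487 in 3D. With chromosome 11 centred, Etv4 in clone 1 stayed at -0.252 ± 0.0690 in 2D (adjusted p = 0.0062). The SE holds the spread between libraries only, and 17.1% of the 802 genes of chromosome 11 were lower than Etv4 in clone 1 in 2D. This value therefore cannot decide whether copy number is the whole cause there. In 3D centring moved Etv4 in clone 1 from -0.48 ± 0.06 to -0.0526 ± 0.0592 (adjusted p = 0.541, and 1.5e-18 to 0.541 over all alternatives). The call in 3D ended because the chromosome's median was nearly as low as Etv4, so copy number of chromosome 11 may be the cause in 3D. In clone 2 the centred values were -0.59 ± 0.07 in 2D (adjusted p = 3.8e-07) and -0.11 in 3D (adjusted p = 0.171), and loss of edited transcripts that differs between formats stays open as untested.

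In total 1102 genes had an interaction past the threshold, and the number was 550 and 415 without control replicate 1 or 2 in 3D, 589 without clone 1 replicate 2 in 3D and 644 without clone 2 replicate 1 in 3D. Etv1 had -0.42 (adjusted p = 0.0050), Neurl3 3.35, C3 3.05, Txnip -1.95, Sparc -1.72 and Id2 -1.48. Bicdl2 had a fitted value of 3.71 and Bspry of 3.52, which are no bounds, since clone 1 had 0.0699 and 0 CPM of them in 2D. Sptb had 4.51, also no bound at 0.206 CPM in control, 0 in clone 1 and 0.0356 in clone 2 in 2D, and it did not pass without control replicate 1 or 2 in 2D (adjusted p = 0.0760 and 0.0737), clone 1 replicate 1 in 2D (0.0607) or clone 2 replicate 1 in 2D (0.0513), with 0.0146 to 0.0760 over all alternatives. Cdkn1a had -1.50 and did not pass without control replicate 1 in 2D (adjusted p = 0.115), clone 1 replicate 2 in 2D (0.259), control replicate 2 in 3D (0.0538) or clone 1 replicate 2 in 3D (0.0513), with 0.0026 to 0.259 over all alternatives. Cplx2 had -1.55 (adjusted p = 0.047) and -0.82 without control replicate 2 in 2D (adjusted p = 0.365, and 0.013 to 0.365 over all alternatives). It did not pass either without clone 1 replicate 1 in 2D (0.0872), clone 2 replicate 1 in 2D (0.0919), or any single 3D library: control replicates 1 and 2 (0.122 and 0.0759), clone 1 replicates 1 and 2 (0.0686 and 0.0982) and clone 2 replicates 1 and 2 (0.0742 and 0.0689). The Cplx2 call was also lost with DESeq2's size factors (0.0539), with genes without overlap (0.0554), without Gm26917 and Gm42418 (0.0587) and with chromosomes centred (0.0717).

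Lists past the threshold in the interaction had medians of -0.4996 for hypoxia (adjusted p = 0.0121 with an estimated correlation), 0.416 for NF-kB (0.0121) and -0.247 for actin and SRF targets (0.0400). The actin mean was -0.0046. Lists that passed with the preset correlation only had medians of 0.172 for PEA3 and ERK feedback genes (adjusted p = 0.2502 with an estimated correlation), -0.165 for matrix components (0.261), -0.164 for the cell cycle (0.192), 0.242 for the interferon response (0.168), 0.0821 for MHC class I (0.200), 0.153 for fatty acid synthesis (0.133), -0.203 for TGF-beta targets (0.261) and 0.113 for ER chaperones (0.169). In the same order their genes higher and lower were 4 and 2 (7 and 2 adjusted over the list alone), 1 and 9 (3 and 12), 0 and 6 (1 and 15), 1 and 0 (0 and 0), 1 and 0 (1 and 0), 0 and 0 (4 and 0), 1 and 5 (1 and 6), and 2 and 0 (4 and 0). With genes that overlap no other gene, PEA3 and ERK feedback genes (adjusted p = 0.0654) and matrix components (0.587) did not pass with the preset correlation.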

How the results depend on the processing

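The fits of genes without overlap, without Gm26917 and Gm42418, and with centred chromosomes were tests chosen after the results were seen, and the other alternatives were planned. Of 299 results for named genes, 268 kept their direction and their side of the threshold under all alternatives run. Genes named only as members of a list that did not pass in that comparison, such as Mmp14 for knockout in 2D, are not among the 299. The exceptions gave 72 values no longer past the threshold, 43 newly past it and 2 reversed, the last with chromosomes centred. They were Etv1 in clone 1 in 3D at -0.20 (adjusted p = 0.0094, and 0.0094 to 0.984 over all alternatives) and Etv4 in clone 2 against clone 1 in 3D at -0.0608 (adjusted p = 0.431, and 5.7e-12 to 0.431 over all alternatives). The medians of chromosomes 12 and 11 that were removed there set these signs.

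Counts of genes past the threshold stayed within 1.5 times in 271 values and moved further in 39. They were 89.5 to 101% of the reported counts with DESeq2's size factors, 78.9 to 98.3% with the DESeq2 test, 94.0 to 113% with the looser filter, 79.8 to 105% with the stricter filter, 86.8 to 99.5% with a replicate block and 89.5 to 102% without Gm26917 and Gm42418. Replicates with the same number in different groups had nothing detectable in common, with correlations of -0.0449 to 0.0223 over 15 pairs of groups.

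With genes without overlap, fewer genes were tested (7883) and fewer passed: 3074 for knockout in 2D, 2597 in 3D, 3447 and 2940 for clone 1 and clone 2 in 2D, 4044 and 2592 in 3D, 3614 and 4770 between the clones in 2D and 3D, 6054 and 6553 for 3D against 2D in control and knockout, 673 for the interaction and 1295 alike in both clones in 2D. With each format fitted alone, 6334 genes passed for knockout in 3D, 6440 for clone 2 in 3D, 1335 alike and 292 opposite in 2D, and 1984 alike and 2395 opposite in 3D, and the cause was not tested. With chromosomes centred, 2398 passed for knockout in 3D and 631 alike in 3D, and the cause was not tested.

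With each library left out in turn, its group's lone library was assumed to vary like the other groups. Counts then ranged over 2109 to 4585 for knockout in 3D, 2429 to 4666 for clone 2 in 3D, 415 to 1407 for the interaction, 332 to 491 opposite in 2D, 521 to 1240 alike in 3D and 679 to 1607 opposite in 3D. Without control replicate 1 or 2 in 3D, the counts were 2224 and 2109 for knockout in 3D, 2590 and 2429 for clone 2 in 3D, 550 and 415 for the interaction, 558 and 521 alike in 3D and 684 and 679 opposite in 3D. Without clone 2 replicate 1 or 2 in 3D, they were 2436 and 2461 for clone 2 in 3D, 590 and 596 alike in 3D and 838 and 829 opposite in 3D. The interaction was at 644 without clone 2 replicate 1 in 3D and 589 without clone 1 replicate 2 in 3D, and the opposite calls in 2D at 332 without control replicate 2 in 2D. The other counts stayed within 1.5 times, such as 4172 to 4888 for knockout in 2D and 9677 to 11075 for 3D against 2D in control.

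The share of higher genes among those called was 35.3% in the interaction, 46.6% with DESeq2's size factors, 53.4% without Gm26917 and Gm42418, 54.1% with chromosomes centred and 52.3% without overlap. For clone 2 in 2D it was 55.7%, and 45.1% with chromosomes centred. List calls kept their side in 140 values and lost it in 67. Depth limits genes with few counts in 2D, where 12.3 to 18.7 M counts were read per library.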

Other observations

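The set of nearly absent genes, the list tests of single clones, and the tests of opposite-strand and same-strand cover were chosen after the results were seen. Among 9248 genes with at least 5 CPM in control in both formats, 13 were below 5% of control in clone 1 in both formats and 0 in clone 2, and 11 of the 13 kept at least 50% of control in clone 2. Rab25, a GTPase of epithelial recycling endosomes, was at 14.5 CPM in control, 0.276 in clone 1 and 22.8 in clone 2 in 2D, and at 19.9, 0.389 and 37.3 in 3D. Cav1 was at 53.0, 1.02 and 51.6 CPM in 2D, Cldn7 at 105, 3.02 and 110 in 3D, and the dystrophin gene Dmd at 6.14, 0.0995 and 11.3 in 3D. The others were Rps6ka6, Bspry, Rasef, Zfp518b, Casp12, Tmem266, Acsl6, Fam111a and Slc39a4, and Slc39a4 was low in clone 2 as well, at 0.793 CPM in 2D and 1.15 in 3D.

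In 3D interferon and antigen presentation genes differed between the clones in the direct tests of clone 2 against clone 1, for MHC class I with 11 of 13 genes higher and 0 lower in clone 2 (11 and 0 adjusted over the list alone, adjusted p = 3.6e-05, and adjusted p = 0.093 with an estimated correlation). In clone 1 interferon response genes were lower in 13 of 21 and higher in 0 (13 and 0 adjusted over the list alone), with Ddx60 at -2.40 ± 0.16, Parp14 at -1.37 ± 0.09 and Gbp2 at -1.62 ± 0.16 (adjusted p = 0.0021, and adjusted p = 0.080 with an estimated correlation). In clone 2 they were higher in 16 and lower in 1 (17 and 1 adjusted over the list alone), with Ifit1, which binds viral RNA, at 1.56 ± 0.18 and Oasl2 at 1.14 ± 0.12 (adjusted p = 7.0e-06, and adjusted p = 0.040 with an estimated correlation). MHC class I genes were lower in clone 1 in 12 of 13 and higher in 0 (12 and 0 adjusted over the list alone), with the immunoproteasome subunit Psmb8 at -2.95 ± 0.24 and the peptide transporter Tap2 (18.5% of its exon length covered on the opposite strand) at -1.56 ± 0.13 (adjusted p = 3.6e-07, and adjusted p = 0.068 with an estimated correlation). In clone 2 they were higher in 3 and lower in 4 (4 and 4 adjusted over the list alone, median -0.06, adjusted p = 0.854). Cell cycle genes in clone 2 in 3D were lower in 20 of 26 and higher in 0 (22 and 0 adjusted over the list alone), with Mcm3 at -0.95 ± 0.05 and Mcm6 at -0.92 ± 0.05 (adjusted p = 2.4e-10, and adjusted p = 0.10 with an estimated correlation). Both genes lie on chromosome 1, whose median in clone 2 in 3D was -0.558, and with chromosomes centred they were at -0.39 and -0.36. In clone 2 in 2D cell cycle genes were higher in 13 and lower in 2 (14 and 2 adjusted over the list alone, median 0.14, adjusted p = 0.0590).

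Genes with over 75% of their exon length covered by a gene on the opposite strand had low medians in 3D against 2D in control. The median was 0.191 at over 0 to 10% cover (2281 genes), -0.338 at over 50 to 75% (120 genes) and -2.28 at over 75 to 95%. In 3D against 2D in control, the 31 genes over 95% covered had a median 6.77 below that of 9166 genes without overlap (difference -6.77, 95% interval -7.38 to -6.01), Pdcd2 and Slirp among the most changed. The 56 genes over 50% covered on the same strand differed by 0.0513 (-0.498 to 0.495). Of these, 34 were over 50 to 75% covered and 1 over 95%. This set has less cover than the 31 genes, so it cannot exclude reads given to both genes in the 2D table. Over 75 to 95% covered, 21 same-strand genes had a median of 0.551 and 38 opposite-strand genes one of -2.28. At that cover the medians argue against reads given to both genes in the 2D table. These values are consistent with reads of the 3D table assigned without strand, as a candidate explanation. Of 1211 genes with at most 12 reads in 2D that lie inside an opposite-strand gene, 248 (20.5%) reached 60 reads in 3D, against 9 of 207 (4.35%) inside a same-strand gene and 487 of 13098 (3.72%) inside none.

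Over 245 such genes the clone 2 against clone 1 change in 3D followed that of the host gene, with a Spearman's rho of 0.637 (95% interval 0.537 to 0.718, permutation p = 1e-05, the smallest possible), and genes are not independent replicates. Signal of such genes in 3D may come from reads of the host. Gene and host lie on the same chromosome, and these values were not centred. The correlation therefore cannot part reads of the host from the chromosome-wide shifts between the clones. Regulation by culture format of genes that overlap no other gene, 6054 of which passed the threshold in control, stays open beside the collagenase step and the separate tables. For 3D against 2D in knockout, 1 of 35 splits of the 8 libraries gave as many genes, the real split with 9019, and the highest other gave 238, the split by clone. This excludes chance only if the libraries can be exchanged freely, since 1 of 35 is the smallest share possible and whole groups of replicates allow too few splits to exclude it.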
